A study of Rattus norvegicus with 90 samples.

How the data were processed

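Total RNA of AR42J cells, a line derived from a rat pancreatic acinar tumour, was labelled and hybridised to Illumina bead arrays, per the labels' protocols. The deposited values are on a log2 scale between 5.51 and 14.84 for 22523 probes on each of 90 arrays, with 0 missing values. They were made with lumi 2.4.0, per the submitters' processing notes. Whether that scale is a plain log2 or a variance-stabilised one is not given in the sources used here, so changes of dim probes are in the deposited unit and need not equal a log2 ratio of intensities. The medians of the arrays lay between 6.403 and 6.406, and at each rank the sorted values of the arrays lay within 0.0267 of each other, so all arrays had nearly the same distribution as deposited. Scanner intensities and detection calls were not analysed here. The number of arrays limits the precision, and the signal over background of a single probe is unknown.

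Stimulus, time and batch of each array were taken from the labels. There were 35 control arrays, 34 with gastrin, 9 with cycloheximide and 10 with gastrin and cycloheximide. The 2 remaining arrays, of batch 3 at 12 h, have a title and a stimulus label that contradict each other, and they entered no comparison between groups. The arrays of batches 1 to 6 numbered 2, 23, 23, 18, 18 and 6. The labels name a batch and do not say that batches were separate cultures, so p-values measure the spread between these samples, which can be technical. Technical replicate arrays of batch 6 were averaged, and their deviations from the mean of all arrays had a correlation of 0.953 with gastrin and with gastrin and cycloheximide. At 1 h, batches 4 and 5 were each measured in 2 title series. The gastrin fits used the mean of the 1 h arrays of a batch and stimulus, and the deviations of such arrays from the mean of all arrays had a correlation of 0.357 to 0.439 between the series. The fits that include cycloheximide used, at 1 h, the series that holds all 4 stimuli.

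Gene names came from the platform annotation of the probes. One symbol was given for 13793 probes and several for 0. The other 8730 probes are unnamed here, and 13337 genes were named. Of the named probes, 13752 matched an entry of the rat gene table of assembly GRCr8 by Entrez identifier, 41 did not, and 0 symbols were changed by it. That table was used for names alone. For 425 genes with more than 1 probe, the probe with the highest mean level stands for the gene, and no other probe of a gene named by the rule below had the opposite sign.

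Differences were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. The gastrin comparisons used control and gastrin samples of all 6 batches with the combination of batch and time as a block, so that each gastrin sample was set against the control of its own batch and time. Effects were averaged over 0.5 to 2 h, over 4 to 8 h, and over 10 and 14 h, and 0.25 h was tested alone. The cycloheximide comparisons used batches 4 to 6 at 1, 2, 4 and 6 h with the same block. The change of untreated cells used the control arrays of batches 2 and 3, and set 8, 10 and 14 h against 0, 0.25 and 0.5 h with the batch as a block. A last comparison set the gastrin effect in batches 4 to 6 against that in batches 2 and 3 at shared times. These designs, the rule for named genes, the gene lists and the alternatives, except those said below to be added, were fixed before the data were examined. The block was part of the design because the labels name the batch. Deviations of control and gastrin samples from the mean of their stimulus and time were correlated at 0.629 to 0.923 within a batch.

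Named genes were the 8 largest rises and the 5 largest falls in each gastrin window, the 6 largest each way in the cycloheximide comparisons and the 5 largest each way in untreated cells. They had to pass the threshold, have 1 symbol that is not a LOC or RGD number, and change in the same direction in every pair of samples. Only 5 rises met this rule in the test of the difference made by cycloheximide. For gene lists, up to 4 members with the largest change were named. The 23 lists held immediate early factors, feedback regulators of MAPK signalling, CREB targets, growth factors and invasion genes, NF-kB and cytokine targets, the unfolded protein response, the ATF4 amino acid response, DNA replication in G1 and S, mitosis in G2 and M, ribosome biogenesis, cholesterol synthesis, glycolysis, apoptosis and survival, p53 targets, the circadian clock, heat shock, gastrin receptor signalling, ribosomal proteins, and markers of acinar, neuroendocrine, ductal, fibroblast or stromal, and immune or endothelial cells. Each list was tested with camera of limma at a preset correlation of 0.01 between genes in 6 contrasts, with adjustment over all 138 tests. Camera with an estimated correlation, fry and the mean of all probes of a gene were alternatives.

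Further alternatives fixed in advance were quantile normalization, median centring, a filter on dim probes at the median level, eBayes with trend and robust options, array weights, no block, batch as an additive block, the 1 h repeat arrays as samples of their own, batches 2 and 3 alone, all 1 h arrays averaged, the addition of batches 1 to 3 to the cycloheximide fits, 14 h against 0 h alone, and each batch left out in turn. After the data had been seen, some arrays were found to stand apart along one axis, and a score for it was defined in 2 ways. The first definition was the first principal component of the control arrays after subtraction of the mean of their own batch and title series, over probes at or above the median level, which held 20.4% of their variance. The second was the mean of the 100 probes that were most raised minus the mean of the 100 most lowered, in both batches 4 and 5, in the 2 h control array against the mean of the 1 and 6 h control arrays. From it the median of the control arrays of the same batch and title series was subtracted. The second is called the array score. Each was used as a covariate, and all arrays with a score above 0.5, a threshold also chosen after seeing the data, were left out, in the gastrin fits with their pairs. That left only 0.5 and 1 h of the 0.5 to 2 h window, the former from batches 2 and 3 and the latter from batches 4 and 5. It left 1, 4 and 6 h in the cycloheximide comparisons, and 4 and 6 h in the comparison between batches 4 to 6 and batches 2 and 3. Dusp10 and Phlda1, which gastrin can move, are among the score probes, so these adjustments can also remove an effect of gastrin. Centring on bright probes of low spread, the lowest 10% of them, and the score and no-block fits of the gene lists were also added after the data had been seen, as was a fit of early and late controls as 2 groups, with both batches and with 1 left out.

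The procedure was tested on simulated data with changes of known size in some of 22523 probes. Changes of 0.5 log2 were recovered in 100% of probes in the 0.5 to 2 h window, in 95.5% at 10 and 14 h and in 77.6% at 0.25 h, with 8, 6 and 13 false calls. The simulation had no array axis of the kind described above, so it excludes nothing about it. It also gave each changed probe the same change in every batch, with independent noise on each array. Recovery and false calls can therefore be worse where effects differ between batches. Regroupings of the samples were limited to 100 per comparison.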

Results

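AR42J cells carry the receptor for gastrin, a peptide hormone of the stomach, and express genes of pancreatic acinar cells. The arrays followed them from 0 to 14 h after gastrin, with an untreated control at each time, and asked which changes also occurred when cycloheximide blocked protein synthesis. Batches 2 and 3 covered 0 to 14 h, batch 1 was measured at 14 h alone, and batches 4 to 6 held all 4 stimuli between 1 and 6 h. All changes are given on the deposited log2 scale with the standard error of the limma fit, and n counts pairs of samples of one batch and time. These pairs come from at most 6 batches at repeated times, so n is not a number of separate replicates. The fit treats the pairs of one batch as independent. Its standard errors and p-values can therefore be too small where an effect differs between batches.

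Some arrays stood apart along one axis of expression in every stimulus group. The array score, defined on control arrays of batches 4 and 5 after the data had been seen, was 2.06 and 2.10 in their 2 h controls by construction and above 0.5 in 17 of 90 arrays. The gastrin arrays of batches 2 and 3 scored 0.770 and 0.895 at 1 h, 1.28 and 1.33 at 1.5 h and 0.71 and 0.72 at 2 h. Their controls scored -0.056 and 0.047 at 1 h, -0.03 and 0.34 at 1.5 h and 0.15 and 0.10 at 2 h. In batches 4 and 5 at 2 h the gastrin arrays scored 0.63 and 0.68, below their controls. The other scores above 0.5 were 1.00 for gastrin at 10 h and 1.19 at 12 h in batch 2, 0.599 for gastrin at 14 h and 1.51 for an array without a group at 12 h in batch 3, 0.533 and 1.31 for cycloheximide at 2 and 6 h in batch 4 and 1.99 for gastrin with cycloheximide at 2 h in batch 5.

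**Figure D1:**
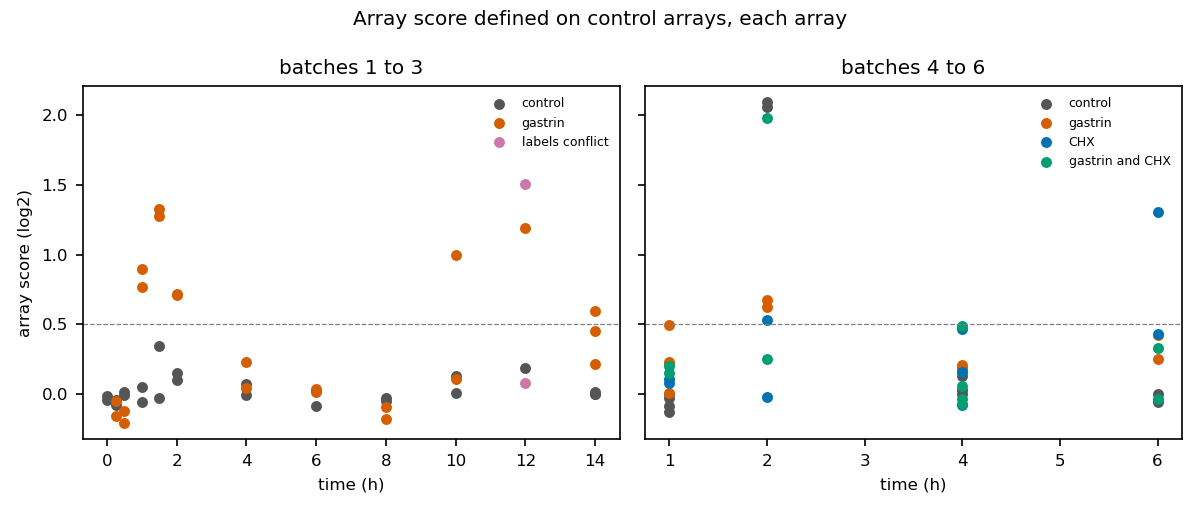
Array score (log2) of each array against time in hours, in batches 1 to 3 (left) and 4 to 6 (right), coloured by stimulus, with the threshold of 0.5 dashed. The 2 h controls of batches 4 and 5 lie at 2.06 and 2.10, while the gastrin arrays of batches 2 and 3 at 1.5 h lie at 1.28 and 1.33.

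At 0.25 h the largest difference between gastrin and control was in Egr1, an immediate early transcription factor. Egr1 was higher by 2.98 and 2.95 in the 2 pairs, and the fitted difference was 2.96 ± 0.53 (SE, n = 2) with a limma adjusted p of 0.104. With limma 0 probes passed the threshold at this time, and 1038 had an unadjusted p under 0.05. Fos and Junb, chosen after their values were seen, differed by 0.90 and 1.05 on average and did not pass. In batches 2 and 3 alone, which hold both pairs, limma called 20 probes, 15 higher and 5 lower. In the fit of all batches with the array score as a covariate it called 2.

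Between 0.5 and 2 h gastrin raised transcription factors of the immediate early class. Egr1 rose by 2.90 ± 0.23 (SE, n = 12), a fold of 7.45, with a limma adjusted p of 6.19e-10. Nr4a3, an orphan nuclear receptor, rose by 1.91 ± 0.20, Nfil3, a repressor that acts in the circadian clock, by 1.82 ± 0.14, and Junb, a component of AP-1, by 1.64 ± 0.14. Chac1, which degrades glutathione, rose by 1.60 ± 0.14, Ier2 by 1.51 ± 0.11, Per1, a clock repressor, by 1.44 ± 0.13 and Nppc, which encodes C-type natriuretic peptide, by 1.44 ± 0.18. All 8 had adjusted p of at most 2.11e-06 in limma and were higher in 12 of 12 pairs. The largest falls were smaller in size. Idh1, an NADPH-producing isocitrate dehydrogenase, changed by -0.54 ± 0.11, Cd83 by -0.50 ± 0.06, the amino acid transporter Slc38a5 by -0.45 ± 0.07, Sesn1 by -0.38 ± 0.08 and Tmem50b by -0.31 ± 0.05, with limma adjusted p between 1.94e-06 and 0.00215.

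The immediate early list had 17 of 25 measured members higher and 0 lower over all probes in this window, and 18 higher when adjusted over the list alone (camera adjusted p = 6.16e-23). Beside Egr1, Nr4a3 and Junb, Fos rose by 2.09 ± 0.17. Of 21 CREB targets 14 rose and 0 fell, also 14 and 0 when adjusted over the list alone (6.04e-19), and the list shares Fos and Nr4a3 with the first. Of 24 feedback regulators of MAPK signalling 14 rose and 0 fell, 15 and 0 adjusted over the list alone (1.16e-11), among them the phosphatases Dusp10 with 1.13 ± 0.20 and Dusp1 with 1.00 ± 0.11 and the mRNA decay factor Zfp36l1 with 0.88 ± 0.09. The circadian clock list had 4 of 13 members higher and 1 lower, and 7 and 1 adjusted over the list alone (0.000103), with Nfil3, Per1 and the repressor Nr1d1 (0.68 ± 0.10) at the top.

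Other lists moved in the same window, and their calls were lost with an estimated correlation. The ATF4 amino acid response had 11 of 25 members higher and 0 lower, and the same counts adjusted over the list alone (camera adjusted p = 6.23e-09, and adjusted p = 0.056 with an estimated correlation). Chac1 led it, followed by the pseudokinase Trib3 with 1.33 ± 0.16 and the mTORC1 inhibitor Ddit4 with 1.14 ± 0.07. Growth factors and invasion genes had 6 of 23 members higher and 0 lower on both counts (0.00882, and adjusted p = 0.0889 with an estimated correlation), including the EGF receptor ligand Hbegf with 0.72 ± 0.06, the plasminogen activator Plat with 0.57 ± 0.09 and Vegfa with 0.45 ± 0.05. Tnfrsf12a of this list was at 0.572 and did not pass without the block (limma adjusted p = 0.608). Replication genes fell in 7 of 25 members and rose in 0, with 10 falls adjusted over the list alone (3.68e-06, and adjusted p = 0.24 with an estimated correlation). Ccne2, a cyclin of S phase entry, changed by -0.37 ± 0.06 and the ribonucleotide reductase subunit Rrm2 by -0.34 ± 0.08. Mitosis genes fell in 4 of 28 members and rose in 0, with 9 falls adjusted over the list alone (0.000832, and adjusted p = 0.349 with an estimated correlation), among them the spindle checkpoint kinase Bub1b with -0.29 ± 0.07 and Cenpf with -0.26 ± 0.05. Without the arrays of high score, a fit that kept 0.5 and 1 h alone, Ccne2 was at -0.21, Rrm2 and Bub1b at -0.04 and Cenpf at -0.12, with limma adjusted p between 0.424 and 0.999.

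In all, limma called 2075 probes in this window, 1055 higher and 1020 lower. In batches 2 and 3 alone it called 5981, 2682 higher and 3299 lower, and it called 3087 without batch 4 and 3095 without batch 5. The count was 1292 with the array score as a covariate, of which 1146 were shared and Rrm2 was not (-0.22, adjusted p = 0.0536), and 88 without the arrays of high score, with 83 higher and 5 lower, where Cd83 (-0.335) alone of the falls named here still passed, and Trib3 (0.65, adjusted p = 0.384), Dusp10, Zfp36l1, Nr1d1 and Plat no longer did. The fit without the arrays of high score kept pairs at 0.5 and 1 h alone, since each pair at 1.5 and 2 h held such an array. The 1 h pairs of batches 2 and 3 held one too. Hence 0.5 h came from batches 2 and 3 alone and 1 h from batches 4 and 5 alone. The values of this fit are therefore of earlier times and, at 1 h, of fewer batches, and a smaller change there need not come from the axis. In that fit Sesn1 was at -0.375, Tmem50b at -0.22, Idh1 at -0.15, Slc38a5 at -0.21, Dusp10 at 0.535, Zfp36l1 at 0.33, Nr1d1 at 0.30 and Plat at 0.23, and Chac1 passed at 0.91. Without batch 2 the count was 230, with 30 lower, and without batch 3 it was 214, with 38 lower, and Idh1, Sesn1, Tmem50b, Dusp10, Plat, Ccne2, Rrm2, Bub1b and Cenpf were lost in both cases and Slc38a5 and Nr1d1 without batch 3. Without the block 141 probes passed, while Junb (adjusted p = 0.0547), Nppc, Dusp1, Zfp36l1, Nr1d1, Hbegf, Vegfa and the falls except Idh1 did not, and the growth factor list had a camera adjusted p of 0.0521. With batch as an additive block 923 passed, but not Cenpf, Ccne2 and Rrm2 (adjusted p = 0.136, 0.115 and 0.0923), and Bub1b and Rrm2 did not with the first principal component (0.156 and 0.294).

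**Figure D2:**
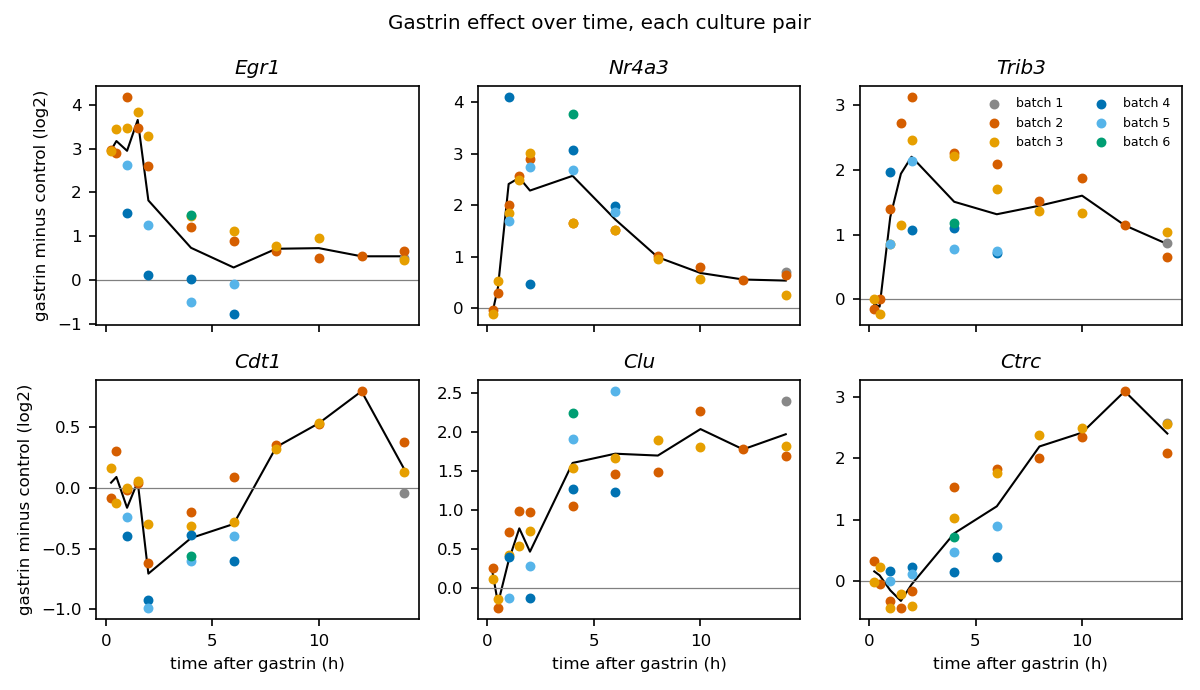
Gastrin minus control (log2) against time in hours for 6 genes, with each point a pair of one batch and time and the line joining the means. Egr1 is highest early, with a mean of 3.65 at 1.5 h, Ctrc reaches 2.42 at 10 h, and Cdt1 is at -0.71 at 2 h and 0.53 at 10 h.

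Between 4 and 8 h Clu, a secreted chaperone, rose by 1.68 ± 0.12 (SE, n = 11), a fold of 3.20, with a limma adjusted p of 1.54e-11. The gene 1810009J06Rikl rose by 2.60 ± 0.10, Nr4a3 by 1.76 ± 0.21, the small GTPase Rrad by 1.65 ± 0.07, the transcription factor Cebpb by 1.62 ± 0.18, the kinase Mylk2 by 1.55 ± 0.08, the trypsinogen Prss3b by 1.52 ± 0.16 and Trib3 by 1.43 ± 0.17. These 8 had limma adjusted p of at most 5.88e-07, and all were higher in 11 of 11 pairs. The falls were led by the receptor tyrosine kinase Ret with -0.88 ± 0.13, the vomeronasal receptor Vom2r65 with -0.69 ± 0.07, Tnfaip8 with -0.69 ± 0.07, the growth factor Vegfc with -0.64 ± 0.05 and Vom2r3 with -0.63 ± 0.08, each lower in 11 of 11 pairs. Vomeronasal receptors and trypsinogens are families of near-identical genes, and cross-hybridisation between their members was not tested.

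The ATF4 amino acid response had 20 of 25 members higher and 0 lower in this window, and 21 higher adjusted over the list alone (camera adjusted p = 8.26e-26). After Cebpb and Trib3 came the transcription factor Atf5 with 1.29 ± 0.12 and asparagine synthetase, Asns, with 1.13 ± 0.07. The unfolded protein response rose in 17 of 25 members and fell in 0, with 19 higher adjusted over the list alone (2.74e-17). Ddit3, a transcription factor of this response, rose by 1.06 ± 0.11, and the endoplasmic reticulum proteins Creld2 by 0.53 ± 0.04 and Herpud1 by 0.49 ± 0.09. CREB targets had 11 of 21 higher and 1 lower, and 13 and 3 adjusted over the list alone (8.89e-08), with Crem at 1.26 ± 0.19 and the phosphodiesterase Pde10a at 1.09 ± 0.10. Of 32 acinar cell genes 11 rose and 4 fell, and 13 and 5 adjusted over the list alone (4.89e-05). The chymotrypsinogen Ctrc rose by 1.40 ± 0.12, the elastase Cela3b by 1.11 ± 0.06 and the trypsinogens Prss1 and Prss3 by 1.00 ± 0.10 and 0.82 ± 0.09.

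Replication genes fell in 18 of 25 members and rose in 0, and 21 fell adjusted over the list alone (camera adjusted p = 1.43e-12, and adjusted p = 0.0538 with an estimated correlation). The helicase subunit Mcm3 changed by -0.44 ± 0.06 and the transcription factor E2f1 by -0.42 ± 0.06. Mitosis genes fell in 14 of 28 members and rose in 0, with 17 falls adjusted over the list alone (3.7e-07, and adjusted p = 0.104 with an estimated correlation), led by the cyclin Ccnb2 with -0.32 ± 0.06. Cholesterol synthesis genes fell in 5 of 17 members and rose in 1, and 8 and 1 adjusted over the list alone (0.00555, and adjusted p = 0.38 with an estimated correlation). Acat2 changed by -0.27 ± 0.06 and Mvd, an enzyme of the mevalonate pathway, by -0.26 ± 0.06. Immediate early factors still had 8 of 25 members higher and 1 lower, 12 and 4 adjusted over the list alone (0.00871, and adjusted p = 0.476 with an estimated correlation). Feedback regulators of MAPK had 3 of 24 higher and 0 lower, 6 and 0 adjusted over the list alone (0.00297, and adjusted p = 0.315 with an estimated correlation). Growth factors and invasion genes had 5 of 23 higher and 0 lower on both counts (0.0174, and adjusted p = 0.118 with an estimated correlation), led by Clu.

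Limma called 2323 probes between 4 and 8 h, 1122 higher and 1201 lower, and 3715 in batches 2 and 3 alone. No control or gastrin array of this window scored above 0.5. Without batch 2 the count was 847 and Herpud1, Acat2 and Mvd were lost, and without batch 3 it was 757 and Acat2, Mvd and Ccnb2 were lost. Without the block it was 225, where Ret and Tnfaip8 (adjusted p = 0.083 and 0.307), Ctrc, Prss1, Prss3, Ddit3, Herpud1 and the falling list members named here no longer passed.

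At 10 and 14 h Ctrc rose by 2.41 ± 0.16 (SE, n = 5), a fold of 5.32, with a limma adjusted p of 3.57e-11. The gene 1810009J06Rikl rose by 2.05 ± 0.14, Clu by 2.01 ± 0.17, Prss3b by 1.63 ± 0.23, the collagen Col18a1 by 1.503 ± 0.085, Cebpb by 1.48 ± 0.25, Cela3b by 1.41 ± 0.08 and Trib3 by 1.23 ± 0.24, each higher in 5 of 5 pairs and with limma adjusted p of at most 0.00177. The acute phase gene Crp changed by -1.03 ± 0.19, the splicing regulator Rbfox1 by -0.82 ± 0.07, Vom2r65 by -0.76 ± 0.10, the pancreatitis-associated lectin Reg3b by -0.72 ± 0.19 and Ret by -0.71 ± 0.19, with limma adjusted p of at most 0.0193. At 12 h the single usable pair, of batch 2, gave no test, and its differences were 3.09 for Ctrc, 1.78 for Clu and -0.88 for Crp.

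The unfolded protein response rose in 15 of 25 members and fell in 0, and in 16 and 2 adjusted over the list alone (camera adjusted p = 5.56e-10). Creld2 rose by 0.60 ± 0.06, Dnajb9, a chaperone of the endoplasmic reticulum, by 0.56 ± 0.12 and the translocon subunit Sec61b by 0.43 ± 0.05. In the ATF4 list 14 of 25 members were higher and 0 lower, and 15 and 1 adjusted over the list alone (3.83e-09, and adjusted p = 0.0551 with an estimated correlation), with Atf5 at 1.02 ± 0.17. Replication genes were now higher in 12 of 25 members and lower in 0, and 15 and 0 adjusted over the list alone (6.6e-10, and adjusted p = 0.0889 with an estimated correlation). Gins1, of the replicative helicase, rose by 0.58 ± 0.08, Orc1, of the origin recognition complex, by 0.53 ± 0.09 and Mcm2 by 0.40 ± 0.09. Cholesterol synthesis genes rose in 6 of 17 members and fell in 0 on both counts (0.00149, and adjusted p = 0.358 with an estimated correlation), with Cyp51 at 0.39 ± 0.09. Acinar cell genes did not pass as a list, with 6 of 32 members higher and 3 lower, and 6 and 4 adjusted over the list alone (0.0713).

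Limma called 1694 probes at 10 and 14 h, 852 higher and 842 lower, and 1054 and 654 with centring on invariant probes, which was chosen after the data had been seen. The count was 1054 with the array score as a covariate, where Ret did not pass (-0.43, adjusted p = 0.096, and 0.106 with the first principal component of the control arrays), and 567 without the arrays of high score, where Reg3b (-0.61, adjusted p = 0.256), Mcm2 (0.31) and Cyp51 (0.32) did not pass and the median standard error was 0.0762, against 0.0612. It was 3612 in batches 2 and 3 alone, 2803 with array weights, 92 without batch 2, 317 without batch 3 and 37 without the block, and Trib3, Crp, Reg3b, Ret, Cyp51, Mcm2 and Dnajb9 did not pass in any of these 3 fits, nor Cebpb and Atf5 without batch 2 or 3, Gins1 and Orc1 without batch 2 or the block, Prss3b without batch 2, or Cela3b, Rbfox1, Creld2 and Sec61b without the block. With batch as an additive block 557 passed, but not Reg3b (adjusted p = 0.512), Ret, Cyp51, Mcm2 and Dnajb9, and with trend and robust options Reg3b and Ret did not (0.0576 and 0.0511).

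The difference between the late and the early window was tested directly, and the genes named for it were chosen after their values were seen. Ctrc was higher late than early by 2.52 ± 0.19 (SE), Clu by 1.66 ± 0.20, Col18a1 by 1.55 ± 0.10 and Gins1 by 0.64 ± 0.10, with limma adjusted p of at most 0.000192. Egr1 was lower late by -2.26 ± 0.41, Fos by -1.73 ± 0.30, Junb by -1.67 ± 0.26 and Nr4a3 by -1.30 ± 0.36, with limma adjusted p of at most 0.0372. The same difference was -0.10 ± 0.29 for Trib3 (adjusted p = 0.937) and 0.39 ± 0.11 for Orc1 (adjusted p = 0.0503). In limma 795 probes passed, 401 higher late and 394 lower late. With the array score as a covariate 1377 passed, among them all 795, and 2014 in batches 2 and 3 alone. Without the arrays of high score, where the early window held 0.5 and 1 h alone, 318 passed. The count was 35 without batch 2, 59 without batch 3 and 6 without the block. Of these 6, 0 were lower late, so Egr1, Fos, Junb and Nr4a3 did not pass without the block. The genes named here were not followed under the other alternatives.

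**Figure D3:**
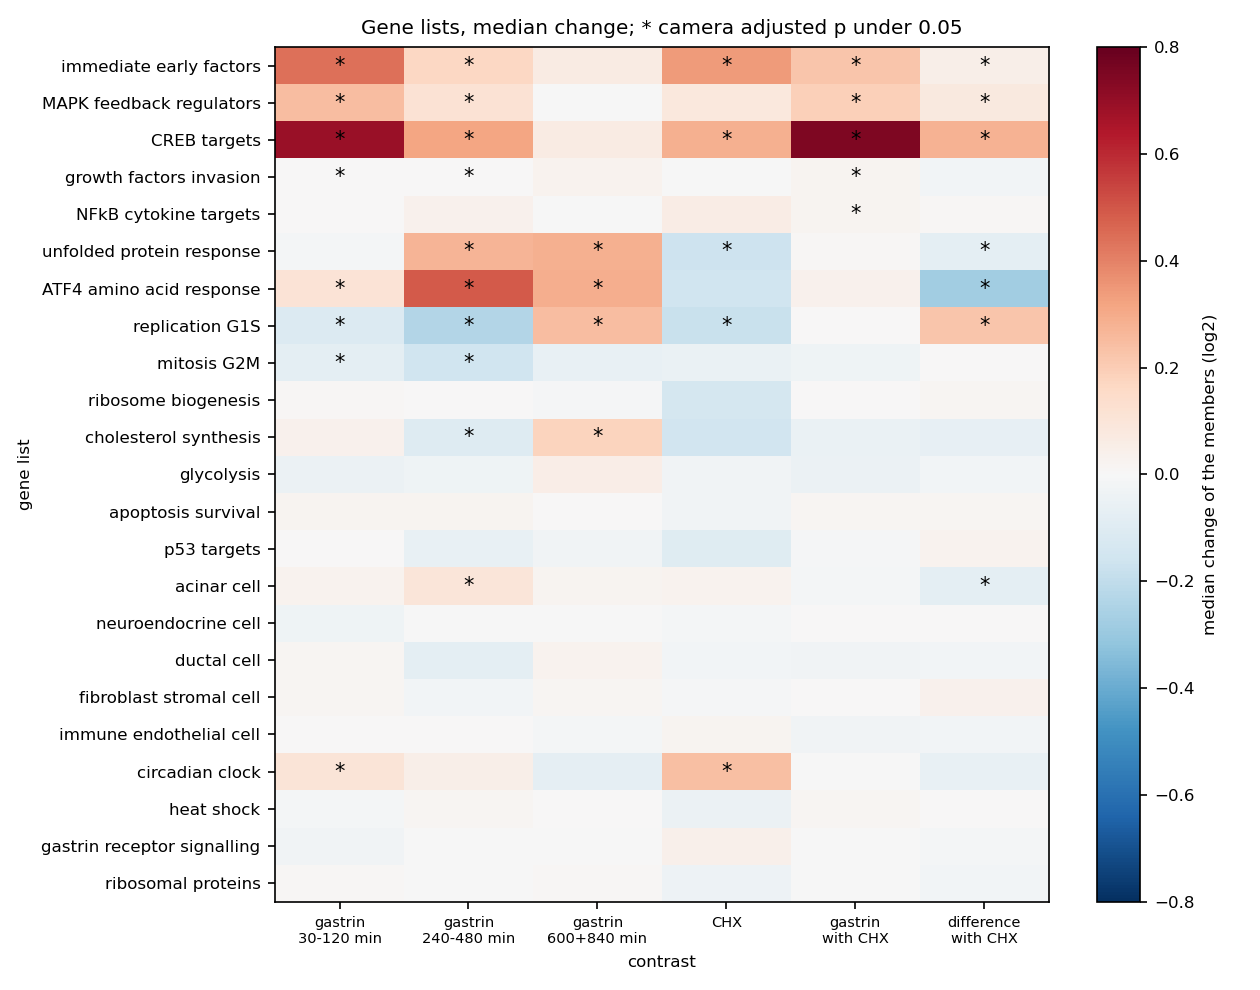
Median change of the measured members (log2, colour) of 23 gene lists in 6 contrasts, with an asterisk where the camera adjusted p is under 0.05. CREB targets have a median of 0.69 at 0.5 to 2 h and 0.75 for gastrin beside cycloheximide, and replication genes -0.24 at 4 to 8 h and 0.25 at 10 and 14 h.

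With cycloheximide alone Txnip, an inhibitor of thioredoxin, rose by 2.98 ± 0.22 (SE, n = 9), a fold of 7.89, with a limma adjusted p of 1.37e-09. Gadd45g, a stress-induced growth regulator, rose by 2.96 ± 0.14, the AP-1 component Jun by 2.55 ± 0.15, Egr1 by 2.49 ± 0.26, Dusp1 by 2.15 ± 0.18 and Taf1d by 2.09 ± 0.15. Falls were led by Lrrn1 with -1.29 ± 0.15, Dnajb9 with -1.26 ± 0.11, the hyaluronidase Hyal2 with -1.14 ± 0.06, Cdca7 with -1.04 ± 0.07, Traf4 with -1.03 ± 0.09 and the lactate transporter Slc16a1 with -1.03 ± 0.06. Each of the 12 genes moved in the same direction in 9 of 9 blocks, with limma adjusted p of at most 8.78e-07.

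Immediate early factors rose in 15 of 25 members with cycloheximide alone and fell in 0, on both counts (camera adjusted p = 8.89e-08, and adjusted p = 0.0536 with an estimated correlation), with Klf10 at 1.93 ± 0.10. CREB targets rose in 10 of 21 and fell in 0 on both counts (0.0023, and adjusted p = 0.287 with an estimated correlation). The clock list rose in 7 of 13 and fell in 1 on both counts (0.000914), with Nr1d1 at 1.93 ± 0.16 and Nfil3 at 1.44 ± 0.14. The unfolded protein response fell in 11 of 25 members and rose in 1, and 13 and 1 adjusted over the list alone (0.00445, and adjusted p = 0.358 with an estimated correlation). Dnajb9 fell most there, and Ddit3 was the member that rose, by 0.77 ± 0.11. Replication genes fell in 13 of 25 members and rose in 0, and 17 and 1 adjusted over the list alone (9.8e-05, and adjusted p = 0.38 with an estimated correlation), with Ccne2 at -0.99 ± 0.13. Limma called 5645 probes, 2617 higher and 3028 lower, and with centring on invariant probes 3281 were higher and 2363 lower. The count was 3075 without batch 5 and 3011 without the block, and all of the 12 genes above passed in both, while Ddit3 did not pass without the block (adjusted p = 0.184).

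Gastrin given beside cycloheximide, set against cycloheximide alone, still raised early transcription factors. Nr4a3 rose by 3.13 ± 0.24 (SE, n = 9), a fold of 8.75, with a limma adjusted p of 5.64e-08. Fos rose by 2.69 ± 0.26, the CREB family repressor Crem by 2.63 ± 0.27, the small GTPase Gem by 2.06 ± 0.24, Per1 by 1.86 ± 0.18 and Rgs2, which limits signalling of G proteins, by 1.63 ± 0.21, all higher in 9 of 9 blocks with limma adjusted p of at most 5.61e-05. The falls were Mycn with -0.64 ± 0.16, Flrt3 with -0.55 ± 0.14, the sterol hydroxylase Cyp8b1 with -0.53 ± 0.10, the SUMO ligase Pias4 with -0.46 ± 0.06, Sema4a with -0.45 ± 0.10 and Cabp7 with -0.45 ± 0.09, with limma adjusted p between 2.57e-05 and 0.0348. In the same batches without the inhibitor, the limma gastrin differences were 2.32 for Nr4a3 (adjusted p = 4e-06), 1.56 for Crem (0.0014), 1.30 for Per1 (0.000156) and 0.86 for Fos (0.0644).

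CREB targets rose in 14 of 21 members beside the inhibitor and fell in 0, and 15 and 1 adjusted over the list alone (camera adjusted p = 8.26e-26). Immediate early factors rose in 8 of 25 and fell in 1, and 9 and 2 adjusted over the list alone (5.92e-10), with Nr4a2 at 1.48 ± 0.18 and Ier2 at 0.80 ± 0.13. Feedback regulators of MAPK rose in 5 of 24 and fell in 0, and 8 and 0 adjusted over the list alone (6.76e-08), with Dusp1 at 0.75 ± 0.18 and Zfp36l1 at 0.74 ± 0.12. Growth factors and invasion genes rose in 4 of 23 and fell in 0 on both counts (0.00973, and adjusted p = 0.0551 with an estimated correlation), namely Plat with 1.09 ± 0.12, Clu with 0.81 ± 0.17, the membrane protease Mmp14 with 0.65 ± 0.09 and Hbegf with 0.65 ± 0.10. NF-kB and cytokine targets rose in 2 of 16 and fell in 0, and 3 and 0 adjusted over the list alone (0.0229, and adjusted p = 0.085 with an estimated correlation), namely Nfkbiz with 1.36 ± 0.12 and Nfkb2 with 0.37 ± 0.10. In limma 477 probes passed beside the inhibitor, 318 higher and 159 lower, and 862 passed without it, 469 higher and 393 lower. Without it 482 passed with all 1 h arrays averaged and 2657 with batches 1 to 3 added. Without batch 5 these counts were 89 and 215, without batch 4 they were 271 and 135, and without the block 95 and 74. Without batch 5 Rgs2, Clu (0.46, adjusted p = 0.487), Hbegf, Zfp36l1, Dusp1, Nfkb2 and the 6 falls no longer passed, without batch 4 Ier2, Dusp1, Nfkb2, Flrt3 and Cabp7 did not, nor Mycn without batch 6, and the fit without the block lost Fos (adjusted p = 0.053), Clu, Mmp14, Hbegf, Ier2, Dusp1, Zfp36l1, Nfkb2 and the 6 falls. Without the arrays of high score Flrt3 (-0.56), Sema4a (-0.47), Dusp1 (0.75) and Nfkb2 (0.51) did not pass, and the median standard error was 0.0557, against 0.0472. That fit averaged 1, 4 and 6 h alone. With batch as an additive block 285 and 452 probes passed, but not Mmp14, Ier2 (adjusted p = 0.419), Dusp1, Nfkb2 and, of the 6 falls, any but Pias4. Flrt3, Dusp1 and Nfkb2 did not pass with array weights or with trend and robust options, nor Mycn (0.117) with the latter.

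Whether cycloheximide changed the gastrin effect was tested as a difference of differences. The gastrin effect on Fos was larger with the inhibitor by 1.84 ± 0.36 (SE, n = 9, limma adjusted p = 0.0399). It was also more positive for Rab19 by 0.53 ± 0.10 and for the replication genes Cdt1 by 0.50 ± 0.08, Orc1 by 0.47 ± 0.09 and Mcm7 by 0.32 ± 0.06. The gastrin difference of Cdt1 was -0.61 without the inhibitor and -0.11 with it. The effect was less positive with the inhibitor for Trib3 by -1.14 ± 0.21, Klhdc8a by -0.88 ± 0.14, the translation repressor Eif4ebp1 by -0.72 ± 0.12, the transcription factor Atf4 by -0.61 ± 0.12, the peptide hormone gene Adm2 by -0.50 ± 0.09 and Cflar, an inhibitor of caspase 8, by -0.49 ± 0.10. The gastrin difference of Trib3 was 1.21 without the inhibitor and 0.07 with it, and that of Atf4 0.61 and 0.00. All 11 genes had the same sign in 9 of 9 blocks, with limma adjusted p between 0.032 and 0.0453.

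In the ATF4 list the gastrin effect was smaller with the inhibitor in 6 of 25 members and larger in 0, and in 13 and 0 adjusted over the list alone (camera adjusted p = 8.09e-14). Beside Trib3 and Atf4 these included Chac1 with -0.92 ± 0.17 and Asns with -0.60 ± 0.11. In the replication list it was more positive in 3 of 25 members and less in 0, and in 13 and 0 adjusted over the list alone (4.86e-20). Among acinar cell genes it was less positive in 1 of 32 and more in 0, with 4 and 0 adjusted over the list alone (5.59e-06). The 1 member was Cela3b with -0.47 ± 0.09. For the unfolded protein response 0 of 25 members passed over all probes and 1 was lower adjusted over the list alone (4.57e-06, and adjusted p = 0.103 with an estimated correlation). CREB targets had 1 of 21 members higher, Fos, and 0 lower, and 5 and 1 adjusted over the list alone (8.76e-07, and adjusted p = 0.0683 with an estimated correlation). Immediate early factors likewise had 1 of 25, and 2 adjusted over the list alone (0.0129, and adjusted p = 0.369 with an estimated correlation). Feedback regulators of MAPK had 0 of 24, and 2 adjusted over the list alone (0.00411, and adjusted p = 0.187 with an estimated correlation).

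Limma called 34 probes in this test, 15 more positive and 19 less positive with the inhibitor. The count was 13 without batch 4, where 0 of the 34 were called, 2 without batch 5, where Trib3 alone of the 11 genes passed, and 17 without the arrays of high score, where Fos and Adm2 alone of the 11 passed. The latter fit averaged 1, 4 and 6 h alone, since the 2 h control and gastrin arrays of batches 4 and 5 were all left out. In it Cdt1 was at 0.33, Trib3 at -1.16, Klhdc8a at -0.81, Eif4ebp1 at -0.71, Atf4 at -0.63, Cflar at -0.48, Rab19 at 0.63, Orc1 at 0.53 and Mcm7 at 0.36, and the median standard error was 0.0747, against 0.0668 in the reported fit. With the array score as a covariate Rab19, Orc1 and Mcm7 had adjusted p of 0.0515, 0.0515 and 0.0518, without batch 6 Rab19, Trib3, Cela3b, Chac1 and Asns did not pass, and Cela3b did not pass without batch 4 or 5. Without the block 0 probes passed, and with batch as an additive block also 0, with adjusted p between 0.0958 for Klhdc8a and 0.68 for Fos among the 11 genes and Chac1, Asns and Cela3b. Trend and robust options left 19, without Fos (adjusted p = 0.174), Trib3 (0.139), Chac1 and Mcm7, and array weights 20, without Atf4 (0.0633), Orc1, Mcm7, Cflar and Cela3b. Orc1, Mcm7 and Cflar did not pass with all 1 h arrays averaged, nor Orc1 (0.28) and Cdt1 (0.30) with batches 1 to 3 added, where 250 probes passed. The immediate early list did not pass without the block (camera adjusted p = 0.177) or with the array score as a covariate (0.0667).

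**Figure D4:**
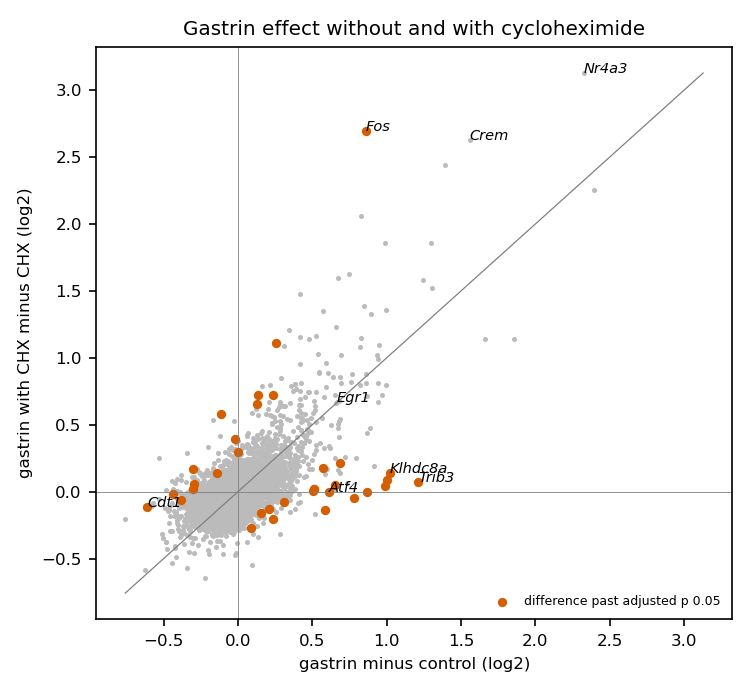
Gastrin effect (log2) without cycloheximide (x axis) against that beside it (y axis), each point a probe and the mean of 4 times, with the line of equality. Orange points are the 34 probes whose difference passed. Fos lies at 0.86 and 2.69, Trib3 at 1.21 and 0.07.

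Control arrays differed over the course as well. In both batches the early controls lie among the first 12 arrays by title number and the late ones after them. A change of the cells with time therefore cannot be told apart from a difference between these groups of arrays. Between the first 0.5 h and 8 to 14 h, Ctrc rose by 1.44 ± 0.21 (SE, n = 2 batches), Clu by 1.28 ± 0.13, the lectins Reg3b and Reg1a by 1.17 ± 0.16 and 1.14 ± 0.08, and Nop53 by 1.09 ± 0.19. Mt3, a metallothionein, changed by -1.03 ± 0.09, the protease Pcsk6 by -0.93 ± 0.05, Bpifa5 by -0.80 ± 0.09, Crp by -0.76 ± 0.07 and adenosine deaminase, Ada, by -0.74 ± 0.08. These 10 had limma adjusted p of at most 0.000503 and the same sign in both batches. The gastrin effects given above are differences from the control of the same time. Limma called 2797 probes, 1301 higher and 1496 lower. With 14 h set against 0 h alone 1048 passed and Nop53 did not (adjusted p = 0.0667), and with the first principal component of the control arrays as a covariate 530, where Ctrc (0.48), Clu (0.42), Bpifa5 (-0.40) and Ada (-0.24) did not pass and Nop53 was at -0.28 (adjusted p = 0.307). With early and late controls fitted as 2 groups, chosen after the data had been seen, 2640 passed, 2209 without batch 3 and 250 without batch 2, where Ctrc (0.95, adjusted p = 0.127), Reg3b and Bpifa5 did not pass.

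The gastrin effect differed between the batches of the inhibitor experiment and batches 2 and 3, with the genes named here chosen after their values were seen. At shared times it was lower in batches 4 to 6 by -1.60 ± 0.20 (SE) for Egr1, by -1.01 ± 0.16 for Fos and by -0.96 ± 0.12 for Junb. It was higher by 0.94 ± 0.08 for Ret, by 0.91 ± 0.07 for Crp and by 0.80 ± 0.09 for Idh1, with limma adjusted p of at most 7.64e-05 for these 6 genes. For Nr4a3 the difference was 0.39 ± 0.25 (adjusted p = 0.339) and for Clu -0.10 ± 0.14 (0.727). Limma called 3621 probes, 1898 higher in batches 4 to 6 and 1723 lower, and with centring on invariant probes 1386 were higher and 2282 lower. With the array score as a covariate 10 probes passed and the median standard error rose from 0.060 to 0.196. Without the arrays of high score, which left 4 and 6 h alone, 840 passed. At 1 and 2 h the comparison holds arrays of high score, so a different gastrin effect and the array axis cannot be told apart there. The count was 1666 without batch 2 and 1626 without batch 3. Without the block 6528 passed, where 1747 of the 3621 were called, 1356 of them with the same sign. In that fit the controls of a time are pooled and cancel, so gastrin arrays of the batches are compared directly. Its count is therefore not one of different gastrin effects.

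Lists not named above passed in none of the 6 contrasts, and their lowest camera adjusted p is given with its contrast. The p53 targets had 0.0526 at 4 to 8 h (0.0268 with the array score as a covariate), with 0 of 15 members higher and 4 lower, and 5 lower adjusted over the list alone. Ribosomal proteins had 0.118 with cycloheximide, with 7 of 26 lower. Glycolysis had 0.176 at 10 and 14 h, apoptosis and survival 0.182 at 0.5 to 2 h, ribosome biogenesis 0.2 and heat shock 0.268 with cycloheximide, and gastrin receptor signalling 0.75 at 0.5 to 2 h. Markers of other cell types were at 0.139 for neuroendocrine cells at 0.5 to 2 h, 0.193 for fibroblasts or stroma and 0.243 for ducts at 4 to 8 h, and 0.514 for immune or endothelial cells in the test of the inhibitor's difference. Camera's direction and the list median had opposite signs in 0 of the 39 list results that passed and in 19 of the 99 that did not. With an estimated correlation 16 of the 39 passed, and these are the ones given without such a p.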

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

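The tests of the 3 patterns weighed here were all chosen after the results had been seen, while the comparisons between windows, between experiments and with the inhibitor were fixed in advance. Of 48 groups of 4 to 10 pairs tested, 4 had 1 value far from the others, and chance gives about 1 in 20 such groups. Rbfox1 at 10 and 14 h was at -0.62 in batch 3 at 14 h, while the other 4 pairs lay between -0.89 and -0.83. Jun with cycloheximide alone was at 1.28 in batch 5 at 1 h, and the other blocks lay between 2.32 and 3.33. In the difference made by cycloheximide, Orc1 was at 1.15 in batch 5 at 4 h, with the others between 0.23 and 0.65. In the same test Cflar was at -1.04 in batch 5 at 2 h, with the others between -0.60 and -0.17.

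The gastrin effect differed between the late and the early window in 795 probes, between batches 4 to 6 and batches 2 and 3 in 3621 probes, and with cycloheximide in 34 probes, each by limma's test of the difference. Signals also lay in the 2 arrays of batch 3 at 12 h that entered no comparison. A gastrin signature, the mean of probes that rose minus that of probes that fell at 4 to 8 h, left out the score probes, was taken relative to the median of the control arrays of the same batch and title series, and was 0.331 in the array titled gastrin and 0.095 in the array titled control.

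The arrays of high score form the first pattern, and gastrin as its whole cause is excluded, since on 100 probes each way chosen in the 2 h control of batch 4 alone that of batch 5 lay at 1.29 and 29 other controls between -0.18 and 0.23, and with probes chosen in batch 5 that of batch 4 lay at 1.75 and the 29 others between -0.28 and 0.33. In batches 2 and 3, 9 gastrin arrays and 0 controls lay above 0.5, and on other probes chosen from those gastrin arrays at 1 to 2 h, which lay at 1.77 to 2, the 2 h controls of batches 4 and 5 lay at 0.65 and 0.30 and 32 other controls at up to 0.57. The 2 h gastrin arrays of batches 4 and 5, which scored 0.63 and 0.68, both lay at 0.51 on these probes. Both scored below their 2 h controls, which define the score. The 1 h ones scored 0.004 to 0.494, each above the control of its batch and title series, and those controls scored -0.128 to 0. These values therefore cannot decide whether gastrin raised the score in batches 2 and 3. The comparison between experiments cannot answer this at 1 and 2 h, since it holds the arrays of high score there. At 4 and 6 h, without such arrays, the gastrin effect differed between the experiments in 840 probes. An effect of gastrin in batches 2 and 3 thus stays open as a cause there. By title number, the highest score of each of 6 groups of 11 or 12 arrays lay at place 8, and in 5 of the 6 by record order, but 2 of these groups define the score and in the other 4 place 8 held arrays at 1.5 or 12 h, 3 of them gastrin arrays and 1 without a group. The place of an array and gastrin treatment therefore cannot be told apart in those 4 groups, and other causes at handling or hybridisation were not tested.

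The second pattern is the contradiction between title and stimulus label at 12 h in batch 3. If the titles were right, the array titled gastrin would have the higher signature, and it was higher by 0.24. With the stimulus labels right the difference between gastrin and control would be -0.24, which is excluded, since from 8 h on 8 control arrays lay between -0.024 and 0.152 and 8 gastrin arrays between 0.256 and 0.55. The control arrays of high score moved this signature by 0.02 and 0.07, less than the gap of 0.1 between the 2 ranges. The values are consistent with exchanged stimulus labels, and both arrays were kept out of the comparisons.

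The third pattern is the smaller gastrin effect with cycloheximide on 6 genes of the ATF4 list, namely Trib3, Chac1, Atf4, Asns, Nupr1 and Slc3a2. Cycloheximide alone could leave no room for a rise, but for the 5 genes other than Atf4 its median effect was -0.46, against 0.65 for gastrin, so such a ceiling is excluded for them as a set. For Atf4 itself cycloheximide alone gave 0.86 and gastrin 0.61, so a ceiling may apply to it. A need for new protein, the biological explanation, cannot be told apart from other effects of the inhibitor, because the genes were chosen for their smaller rise, and 0 of the 6 passed with gastrin beside cycloheximide. The call of this difference also depended on batches 4 and 5, and 0 probes passed with batch as an additive block or without the block.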

How the results depend on the processing

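The fits with the array score, with the first principal component of the control arrays, without arrays of high score and with invariant-probe centring, those of early and late controls as 2 groups, and the score and no-block fits of the gene lists, were chosen after the data had been seen, and the others in advance. Of 3598 values under the alternatives, for 206 combinations of gene and comparison with 125 different genes, 3188 kept their direction and side of the threshold, 33 newly passed, 371 no longer passed and 6 changed sign. Quantile normalization and median centring tested nothing, since the first moved no value by more than 0.000611 and the array medians lay between 6.403 and 6.406. Their 206 values each are among the 3188 and add nothing to the stability. Invariant-probe centring moved the share of higher calls by over 10 percentage points at 10 and 14 h (1054 higher and 654 lower), for cycloheximide (3281 and 2363) and between experiments (1386 and 2282). It, the filter on dim probes and the 1 h repeats as samples of their own moved no count by over 1.5 times. Signal over background is unknown, so how far it limits dim probes is open. With 1 batch left out, the change of controls was fitted with early and late as 2 groups, since 1 mean per time leaves no residual degrees of freedom, and gave 250 without batch 2 and 2209 without batch 3 (2640 with both). Except where said, the cause was not tested.

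With the block of batch and time removed, limma counts were 141 at 0.5 to 2 h (2075 with it), 225 at 4 to 8 h (2323), 37 at 10 and 14 h (1694), 6 for late minus early (795), 3011 for cycloheximide (5645), 95 for gastrin beside it (477), 74 for gastrin without it (862), 0 for the difference (34, with 1713 at unadjusted p under 0.05 in the reported fit) and 6528 between experiments (3621). The count between experiments without the block compares gastrin arrays of the batches directly, since the pooled controls cancel. It is not a count of different gastrin effects. The median standard error at 0.5 to 2 h rose from 0.041 to 0.0524 while the median size of the calls stayed at 0.21. With batch as an additive block the counts were 923, 1278 and 557 in the 3 windows, 222 for late minus early, 285 for gastrin beside cycloheximide, 452 without it, 0 for the difference and 984 between experiments. Elsewhere the block changed no count by over 1.5 times.

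Trend and robust options gave 19 for the difference made by cycloheximide. Array weights gave 1 at 0.25 h (0 reported), 2803 at 10 and 14 h, 1226 for late minus early and 20 for the difference. Batches 2 and 3 alone gave 20 at 0.25 h and 5981, 3715 and 3612 in the 3 windows, and 2014 for late minus early. All 1 h arrays averaged gave 482 for gastrin without the inhibitor. Batches 1 to 3 added gave 2657 for it and 250 for the difference, where Dusp10 was -0.07 and Canx 0.086, of opposite sign to the reported fit. The contrast of 14 h against 0 h alone gave 1048 for untreated cells (2797).

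With the array score counts were 2 at 0.25 h, 1292 at 0.5 to 2 h, 1054 at 10 and 14 h, 1377 for late minus early and 10 between experiments, where the standard error rose from 0.060 to 0.196. With the first principal component they were 1, 913, 1067, 1439 and 175, and 530 for untreated cells, with Nop53 at -0.284. This component was built from the same control arrays, so it removes part of that change by construction. Without arrays of high score they were 1, 88, 567 and 318, then 17 for the difference and 840 between experiments, and in the difference Dusp10 was -0.197 and Phlda1 -0.026, of opposite sign. This fit averaged other times than the reported one, namely 0.5 and 1 h in the early window, 1, 4 and 6 h with cycloheximide and 4 and 6 h between experiments. In the early window it held batches 2 and 3 alone at 0.5 h and batches 4 and 5 alone at 1 h. Sizes in the 2 fits are therefore not of the same times there, nor of the same batches at 1 h in the early window. In the early window the median standard error was 0.0622, against 0.041 reported, and the median size of the reported calls was 0.0963, against 0.21. At 10 and 14 h this size was 0.259 (0.294 reported), for late minus early 0.326 (0.373), between experiments 0.156 (0.255), for cycloheximide 0.291 (0.268), for gastrin beside it 0.372 (0.316), for gastrin without it 0.272 (0.269) and for the difference 0.56 (0.49), and at 4 to 8 h 0.225 in both fits.

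Leaving out 1 batch at a time gave 0 to 1 at 0.25 h (1 without batch 4), 214 to 3095 at 0.5 to 2 h (without batches 3 and 5), 757 to 2527 at 4 to 8 h (3 and 4), 92 to 1982 at 10 and 14 h (2, and 4 or 5) and 35 to 940 for late minus early (2 and 4). It gave 3075 to 5272 for cycloheximide (5 and 6), 89 to 432 for gastrin beside it (5 and 6), 135 to 584 for gastrin without it (4 and 6), 2 to 29 for the difference (5 and 6) and 1626 to 3625 between experiments (3 and 6). Without batch 2 the 3 windows from 0.5 h on had 230, 847 and 92, and the comparison of experiments 1666. Nfkbie with gastrin beside cycloheximide was -0.039 without batch 5, of opposite sign, and 0.174 without batch 4. Of the list tests, 39 passed in camera, 16 with an estimated correlation and 60 with fry, which asks another question.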

Other observations

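The descriptions of gene lists here use the lists fixed in advance, and the splits of the cycloheximide comparisons, of untreated cells and between experiments were tests chosen after the results were seen, while those of the gastrin windows were not. The gene of the gastrin receptor, Cckbr, rose at 0.5 to 2 h by 0.73 ± 0.10 (SE, n = 12, limma adjusted p = 5.22e-06), in 12 of 12 pairs. It was at 0.27 at 4 to 8 h (adjusted p = 0.103) and 0.00 at 10 and 14 h (0.994), and the late minus early difference was -0.72 ± 0.17 (0.0118). Beside cycloheximide Cckbr rose by 0.55 ± 0.12 (0.0101), in 8 of 9 blocks, and the difference made by the inhibitor was 0.12 (0.941). The list of receptor signalling that holds it had 1 member higher and 1 lower at 0.5 to 2 h and did not pass. Cckbr was not followed under the alternatives, some of which cut the calls of this window from 2075 to 88 (without the arrays of high score) or 214 (without batch 3).

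The circadian clock list did not pass at 10 and 14 h (camera adjusted p = 0.148, or 0.00683 with the array score as a covariate), with 2 of 13 members higher and 4 lower, and 3 and 6 adjusted over the list alone. Per2, a repressor of the clock, fell by 0.58 ± 0.09 (SE, n = 5, limma adjusted p = 0.000127), in 5 of 5 pairs, and Nr1d1 fell by 0.51 ± 0.15 (0.0307). At 0.5 to 2 h Nr1d1 was at 0.68, and it did not pass without batch 3 (limma adjusted p = 0.0783) or the block (0.262). Without the arrays of high score, which left 0.5 and 1 h alone, it was at 0.30 (0.11). The late minus early difference of Nr1d1 was -1.19 ± 0.18 (0.000145).

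Other splits exchanged the stimuli within single blocks of batch and time, the early and late labels of untreated arrays within a batch, or the batches between experiments, and the number of probes called was compared with the real one. Blocks of one batch were exchanged independently, and exchange of whole batches would leave too few splits for a share under 0.05, so a chance effect shared by a batch is not excluded. The shares include the real split and were not adjusted over the comparisons. At 0.5 to 2 h 3 of 100 splits called as many as the real 2075. This share lies under 0.05, which makes chance in single blocks unlikely. The highest other split called 3925, more than the real one, so chance is not excluded there. That split exchanged the 2 h pairs of batches 4 and 5, whose controls have the high scores, which points to a structure of the arrays. At 4 to 8 h chance in single blocks is excluded, with 1 of 100 splits, the real one (2323, highest other 681). For late minus early 2 of 100 splits called as many as the real 795. The highest other called 1657 and exchanged 8 pairs, among them the 2 h pairs of batches 4 and 5. These splits stand for no gastrin effect at any time and not for equal effects early and late, so they cannot decide about chance in this difference. Chance in single blocks is also excluded for cycloheximide, with 1 of 100 (5645, highest other 4540), and for gastrin without it, with 1 of 100 (862, highest other 416). For gastrin beside cycloheximide the share was 2 of 100, under 0.05. The highest other split called 734, more than the real 477, so chance is unlikely there but not excluded. That split exchanged the 2 h block of batch 5, whose array with gastrin and cycloheximide has a high score. For the difference made by the inhibitor 2 of 100 splits called as many as the real 34, but this share cannot decide. Where batches were exchanged differently at one time, the large effect of cycloheximide itself entered the spread, which lowers the count whatever the difference. The highest other split called 94, more than the real one, and exchanged the 1 and 6 h blocks of both batches 4 and 5. Those are all the blocks of these times, so this split sets the difference at 2 and 4 h against that at 1 and 6 h. It measures a change of the difference with time and no regrouping within a time, and the cause of the 94 was not tested. Since the share cannot decide, chance is not excluded for this difference. In the real split 0 probes passed without the block or with batch as an additive block. For untreated cells a chance order of arrays within a batch is excluded, with 1 of 100 (2797, highest other 1441). A difference between the groups of arrays by title number is not excluded by these splits. At 10 and 14 h the 16 splits are too few for a share under 0.05, and 1 split, the real one, gave 1694, with 308 the highest other. Between experiments the 10 splits are likewise too few, with 1 at 3621, the real one, and 3217 the highest other, which set batches 4 and 5 against 2, 3 and 6. That split differs from the real one only in the side of batch 6, which was measured at 4 h alone. The remaining splits called 0 to 4 probes.

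The 2 arrays without a group had array scores of 1.51 and 0.08, the first in the array titled gastrin.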
